A study of Mus musculus with 8 samples.

How the data were processed

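RNA from the dorsal skin of 8 male SKH-1 mice, a hairless strain, was hybridised to 8 1-colour (Cy3) Agilent mouse arrays. Per the labels, 4 mice received enalapril maleate and 4 the ethanol vehicle alone after UVB irradiation, and only RNA of adequate integrity was used. The scanner text files hold a spot intensity on a linear scale, which per the file headers came from Agilent Feature Extraction 9.1.3.1 (the submitters' processing notes give version 9.1). Per the file headers, the processed intensity was background-subtracted and detrended within each array, with a surrogate value where a spot was not above background, and was not scaled between arrays. The deposited 0 or 1 flags of the same software, such as well above background and outlier, are other values used as filters. The deposited series matrix holds log2 values. Set against the scanner files they were the log2 of the processed intensity with no centring, with medians between 6.39 and 7.30 per array. Any further step by the authors is not stated in the labels.

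Each array had 45018 spots, of which 43379 were not controls. Spots with an outlier flag were removed, spots of the same probe were averaged on the log2 scale, and 47 of 41174 probes were left out because every spot was flagged on some array. Probe names were updated through a reference table of the GRCm38.p6 assembly, used for names only. By accession 22951 probes matched, by symbol 6650 and by synonym 3084; 2024 kept the name in the file and 6465 stayed unnamed. Among the accession matches, 5141 carried another name in the file. No coordinates are given, because the array files name no genome build. One probe represented each gene, the one with the highest mean signal over the 8 arrays, and unnamed probes were kept one by one.

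The value of a probe was log2 of the processed intensity minus the array's 75th percentile over non-control spots. Levels therefore stand relative to that percentile, and a level of one probe is not set against that of another. Genes were tested where the probe was well above background on at least 4 of the 8 arrays. Tests used limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table for reading. The model had the group as its only term, and limma's moderated test (lmFit and eBayes) was two-sided with Benjamini-Hochberg adjustment. A gene is called changed at an adjusted p under 0.05, and errors given with log2 changes are limma's standard errors over 4 arrays per group. The number of arrays limits the precision.

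Gene lists, 38 in all, covered the renin-angiotensin system, extracellular matrix, inflammation, keratinocytes, skin appendages, cell types, proliferation, stress, the circadian clock, oxidative phosphorylation and ribosomal proteins. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 5 measured members. The estimated correlation and fry were run as alternatives. A list's shift is the median log2 change of its members minus that of all tested genes. Counts of members are over all genes tested and, in a separate adjustment, over the list alone. Profile separation, the mean distance between arrays of different groups minus that within groups, was tested by an exact permutation test over all 35 splits, one-sided.

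Genes named in the text were the 12 largest rises and 12 largest falls past the threshold whose groups did not overlap, leaving out clone, predicted and accession-like names. Up to 4 members with the smallest p were named in each list described, and Ace, Agt, Agtr1a and Bdkrb2 whatever their value. Any other gene is said to be chosen after its values were seen. A gene not well above background on any array of 1 group has only a bound there. The bound sets the mean of the bright group against, on each array of the dim group, the higher of 2 values: the lowest signal among probes well above background and the probe's own.

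The groups, the test, the lists, the naming rule and the alternatives not marked otherwise were set before the data were examined. The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the series matrix values, other filters on dim probes, and every probe or the mean of a gene's probes. Further ones were an intensity trend with robust estimation, array weights, the replicate number as a block, each array left out in turn, an adjusted p under 0.10, and a fold of at least 1.5. Centring on 10 E1A control probes, a filter for probes well above background on all 8 arrays, and a repaired normexp were chosen after seeing the data. In the repaired normexp, the local background of 6 spots on enalapril 3 that lay far above the spot itself was set to that array's median background. Slide and scan as blocks could not be fitted, because each slide and scan held 1 group.

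The pipeline was tested on simulated data with 200 changed genes among 19104. It called 8% of genes changed by 0.5 log2, 54% at 1, 78% at 1.5 and 92% at 2, and 4.07% of its calls were unchanged genes. The simulated noise was independent between genes, without a slide effect, and fewer genes were changed than were called in the data. These rates may therefore not hold for the data. Red blood cell markers, with 4 measured members, were too few to test. Control spots were left out of all tests.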

Results

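Gene expression was measured in dorsal skin of male SKH-1 hairless mice, 19 weeks old, whose backs had been irradiated with UVB for 10 weeks. Starting 1 week after the last irradiation, 4 mice had 1% w/v enalapril maleate in 30 vol % ethanol applied to the skin 5 times a week for 2 weeks, and 4 mice had the ethanol alone. These are the terms of the sample labels; the series description also mentions 6 weeks of treatment and 6 mice per group. Enalapril is an inhibitor of angiotensin-converting enzyme, which makes angiotensin II. Between 67.1% and 72.7% of spots per array were well above background, and no probe was saturated. The 75th percentile of the processed intensity lay between 821.5 and 1540. All 4 vehicle arrays were on slide 1 and in scan 1, and all 4 enalapril arrays on slide 2 and in scan 2, so slide and treatment cannot be told apart in any difference given here. Median local background was 57.5 to 66 intensity units on the vehicle arrays and 48 to 52 on the enalapril arrays.

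The comparison of enalapril with vehicle asks what local inhibition of the enzyme changes in UVB-exposed skin. The circadian clock genes Dbp, Tef and Per2 fell with enalapril, while the clock activator Arntl rose. The skeletal muscle genes Mylpf and Tnnt3, Slc2a4 of the adipocyte list, and the respiratory chain genes Uqcrc1 and Cox5b fell as well. Elastin, both measured fibrillins, and collagens VI and XII rose. Angiotensinogen (Agt), the precursor of angiotensin II, also fell. Agt, the fibrillin gene Fbn2 and the collagen VI gene Col6a2 each kept their call in only 1 of 8 fits with an array left out. Of 19104 genes tested, 2707 changed, 826 being higher and 1881 lower in enalapril, so that 30.5% of the changed genes were higher. By quantile normalization 42.1% of 1857 changed genes were higher, and by the uncentred series matrix values 5.16% of 1998. The median log2 change of all tested genes was −0.08 as reported and −0.45 in the series matrix values, and list shifts below are relative to it. At least a 1.5-fold change was seen in 1360 of the changed genes, 513 higher and 847 lower.

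The whole profile separated the groups. Arrays of different groups lay 16.0 log2 units further apart than arrays of the same group, with p = 0.0286 (exact permutation test over 35 splits, one-sided). All 4 arrays of one group lay above all 4 of the other for 4206 genes, 22.0% of those tested, where chance gives 2.86%. The enalapril 4 array stood apart from the others of its group, and without it 4942 genes changed. Without vehicle 1, 2 or 4 the counts were 875, 929 and 1084, and without enalapril 1, 2 or 3 they were 917, 844 and 904. Among the 78 named genes past the test, 35 kept their call in every such fit that tested them. Named genes not well above background on any array of 1 group were tested in only 4 of these fits, never without an array of their bright group. Centring on E1A control probes ended 50 of the 78 calls, and quantile normalization and the series matrix values ended 20 each.

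**Figure D1:**
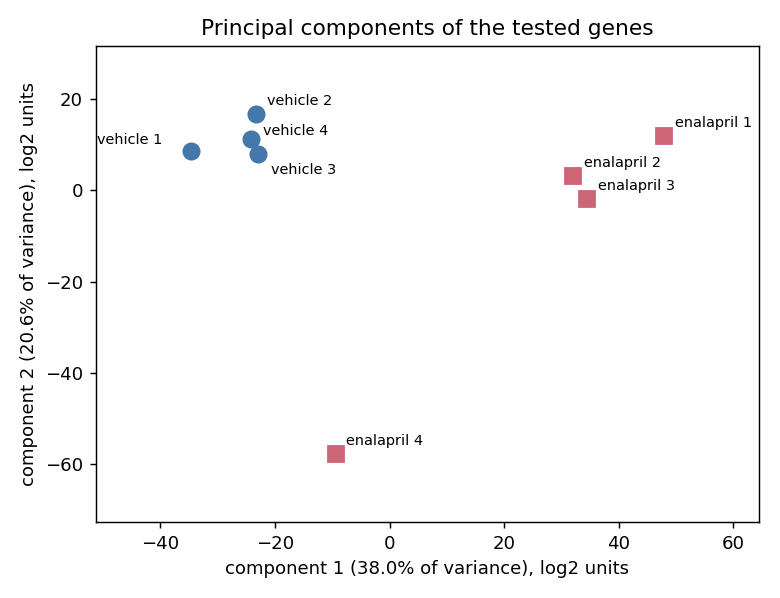
Scores of the 8 arrays on the first principal components of the tested genes, in log2 units, which hold 38.0% and 20.6% of the variance. Enalapril 4, at −9.40 on component 1 and −57.90 on component 2, lies away from the other 3 enalapril arrays, which score between 32.1 and 48.0 on component 1.

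Single circadian clock genes passed in both directions, the rise over all genes being that of Arntl alone. Arntl, which encodes the activator BMAL1, rose by 1.28 ± 0.19 log2, or 2.42-fold (adjusted p = 0.0107). Dbp, a transcription factor driven by that activator, fell by 2.41 ± 0.42 log2, or 5.32-fold (adjusted p = 0.0139). Its relative Tef fell by 1.15 ± 0.22 (adjusted p = 0.0169), and the repressor gene Per2 fell by 1.46 ± 0.31 (adjusted p = 0.0222). For each of these 4 genes, all 4 enalapril arrays lay on the same side of all 4 vehicle arrays. Of 16 clock genes measured, 1 rose and 7 fell over all genes, and 2 rose and 10 fell adjusted over the list alone. The list as a whole, whose members moved both ways, had a shift of −0.61 that did not pass (camera adjusted p = 0.0788; adjusted p = 0.882 with an estimated correlation). It passed in 11 of 22 alternatives, with a range of 0.00015 to 0.315 over all 22. Among the 11 were the fits without vehicle 1 (0.0447), vehicle 2 (0.0367), enalapril 1 (0.0199) or enalapril 3 (0.0303) and that with quantile normalization (0.0329). Arntl, Dbp and Tef kept their calls with each array left out, while Per2 lost its call without vehicle 1, vehicle 4 or enalapril 2, with adjusted p up to 0.0569. Another probe of Per2 gave −0.51 (adjusted p = 0.0859).

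**Figure D2:**
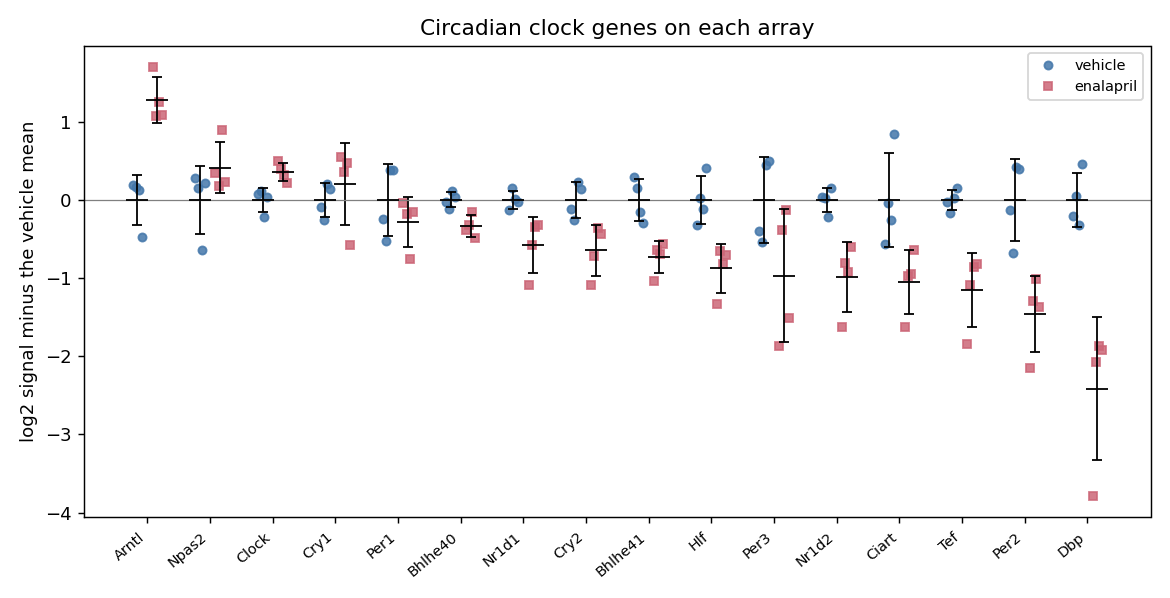
Log2 signal of the 16 clock genes on each array minus the vehicle mean of that gene, as points for the 4 vehicle and 4 enalapril arrays, with the mean and SD as bars. Arntl lies higher on all 4 enalapril arrays, and Dbp, Tef and Per2 lie lower on all 4.

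Skeletal muscle genes stood lower than other genes. Mylpf, a myosin light chain gene of fast fibres, fell by 0.85 ± 0.14 log2 (adjusted p = 0.0128), and Tnnt3, a fast troponin T, by 0.76 ± 0.15 (adjusted p = 0.0176). Tnnc2 fell by 0.69 ± 0.14 (adjusted p = 0.0187) and Pvalb by 0.90 ± 0.18 (adjusted p = 0.0207). Of 19 members measured, 9 fell over all genes and 13 adjusted over the list alone, and none rose. The list stood 0.58 log2 below all genes (shift −0.58, camera adjusted p = 0.00023; adjusted p = 0.882 with an estimated correlation). Tnnc2 lost its call without vehicle 1, enalapril 1 or enalapril 2 (up to 0.0534), and Pvalb without vehicle 1, enalapril 2 or enalapril 3 (up to 0.0579).

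Adipocyte genes also stood lower. Slc2a4, the insulin-responsive glucose transporter, fell by 0.77 ± 0.13 log2 (adjusted p = 0.0139), and Pck1, which serves glycerol synthesis in fat cells, by 0.62 ± 0.12 (adjusted p = 0.0178). The lipid droplet gene Cidec fell by 0.76 ± 0.16 (adjusted p = 0.0207) and Gpd1 by 0.56 ± 0.13 (adjusted p = 0.0264), while another probe of Gpd1 gave −0.05 (adjusted p = 0.907). Of 17 members measured, 7 fell over all genes. Adjusted over the list alone, 7 fell and 1 rose. The shift was −0.38 (camera adjusted p = 0.00561, or 0.882 with an estimated correlation). Over 22 alternatives the shift ran from −0.79 to −0.23. The skeletal muscle list stood lower on the same arrays (shift −0.58), and which tissue the fall of Slc2a4 came from was not tested. Slc2a4 kept its call with each array left out, while Pck1 lost it without enalapril 1 or 2 (up to 0.0540), Cidec without vehicle 1 or 4 or enalapril 1, 2 or 3 (up to 0.0594), and Gpd1 without vehicle 1, 2 or 3 or enalapril 1, 2 or 3 (up to 0.0707).

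Genes of oxidative phosphorylation stood lower than other genes, on arrays where the lists of skeletal muscle (shift −0.58) and adipocytes (−0.38) were lower too. Uqcrc1 of complex III fell by 0.61 ± 0.10 log2 (adjusted p = 0.0127) and Cox5b of complex IV by 0.62 ± 0.11 (adjusted p = 0.0156). Sdhb of complex II fell by 0.45 ± 0.10 (adjusted p = 0.0231) and Ndufb8 of complex I by 0.51 ± 0.11 (adjusted p = 0.0244), with −0.16 (adjusted p = 0.386) on another probe of Ndufb8. Of 28 members, 9 fell over all genes and 16 adjusted over the list alone, with none rising. The shift of −0.27 passed (camera adjusted p = 0.00023; adjusted p = 0.882 with an estimated correlation), and lost its call by quantile normalization at −0.13 (0.119, in a range of 1.6e-09 to 0.119). Ribosomal protein genes shared the direction, with Rpl37 falling by 0.74 ± 0.11 (adjusted p = 0.0116) and Rpl18 by 0.57 ± 0.10 (adjusted p = 0.0146). Rps15 fell by 0.61 ± 0.12 (adjusted p = 0.0170) and Rpl13a by 0.71 ± 0.14 (adjusted p = 0.0173). Over all genes 6 of 30 fell, and 8 adjusted over the list alone. Their shift of −0.17 (camera adjusted p = 0.00359; 0.882 with an estimated correlation) lost its call by quantile normalization (−0.09, 0.107) and without vehicle 4 (−0.08, 0.0709). Sdhb lost its call without vehicle 1, 2 or 4 or enalapril 1 or 3 (up to 0.0669), Ndufb8 without vehicle 1, 2 or 4 or enalapril 1, 2 or 3 (up to 0.0685), and Rps15 without vehicle 1 (0.0507). Both lists are bright on the array, and in the brightest of 5 equal classes of tested genes 28 changed genes were higher and 668 lower, against 103 and 183 by quantile normalization.

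In the list of fibrillar collagens and their processing, the members that passed were genes of collagens XII and VI. No gene of the fibrillar collagens I, III or V passed. Col12a1 rose by 0.62 ± 0.11 log2 (adjusted p = 0.0138), Col6a1 by 0.64 ± 0.14 (adjusted p = 0.0229) and Col6a2 by 0.61 ± 0.16 (adjusted p = 0.0368). The collagen crosslinking enzyme gene Lox, at 0.53 ± 0.15 (adjusted p = 0.0503), did not pass. Over all genes 3 of 24 rose, and 4 did adjusted over the list alone. The shift was 0.21 (camera adjusted p = 0.00401; adjusted p = 0.882 with an estimated correlation), and the list lost its call with array weights (0.15, 0.0987, in a range of 3.1e-05 to 0.999). Skeletal muscle and adipocyte lists stood lower on the same arrays (shifts −0.58 and −0.38). A second tested probe of Col6a2 gave −0.02 (adjusted p = 0.962). Col12a1 kept its call with each array left out. Col6a1 lost its call without vehicle 1, 2 or 4 or enalapril 3 (up to 0.0588), and Col6a2 in each fit but the one without enalapril 4 (up to 0.0899).

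Single elastic fibre genes rose, although their list did not pass. Elastin itself, Eln, rose by 0.78 ± 0.12 log2 (adjusted p = 0.0118), the microfibril gene Fbn1 by 0.85 ± 0.16 (adjusted p = 0.0174), and Fbn2 by 1.02 ± 0.26 (adjusted p = 0.0354). Fbln1 went the other way and fell by 0.43 ± 0.11 (adjusted p = 0.0343). Of 20 members, 4 rose and 1 fell over all genes, and 5 rose and 2 fell adjusted over the list alone. The list, with members going both ways, did not pass (shift 0.15, camera adjusted p = 0.253), except by quantile normalization (0.0438) and without enalapril 2 (0.0317), in a range of 0.0317 to 0.999. Eln and Fbn1 kept their calls with each array left out. Fbn2 kept its call only without enalapril 4 (otherwise up to 0.0823), and Fbln1 lost it without vehicle 1, 2 or 4 or enalapril 1, 2 or 3 (up to 0.0924).

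The TGF-beta response list split in a similar way. The matrix genes Fn1 and Tnc rose by 0.52 ± 0.11 log2 (adjusted p = 0.0236) and 0.70 ± 0.17 (adjusted p = 0.0334), and the smooth muscle gene Tagln fell by 0.52 ± 0.10 (adjusted p = 0.0174). Postn, at 0.45 ± 0.14 (adjusted p = 0.0616), did not pass. Of 20 members, 2 rose and 1 fell, the same as adjusted over the list alone, and the list did not pass (shift 0.11, camera adjusted p = 0.253). The other tested probes gave 0.88 and −0.19 for Fn1, 1.04 and 0.29 for Tnc and −0.16 for Tagln. Without vehicle 1 or enalapril 2, Tagln lost its call (up to 0.0549), Fn1 lost it without vehicle 1 or 2 or enalapril 2 or 3 (up to 0.0646), and Tnc without vehicle 1, 2 or 4 or enalapril 1, 2 or 3 (up to 0.0859).

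Basement membrane genes stood higher than other genes as a list although no single member passed, on arrays where the skeletal muscle and adipocyte lists stood lower (shifts −0.58 and −0.38). Lamb1 was at 0.45 ± 0.15 log2 (adjusted p = 0.0707), Col4a1 at 0.40 ± 0.15 (adjusted p = 0.105) and Col4a2 at 0.46 ± 0.18 (adjusted p = 0.124). The shift over 15 members was 0.24 (camera adjusted p = 0.0125; adjusted p = 0.882 with an estimated correlation), with 0 members passing adjusted over the list alone. Basal keratinocyte genes were higher by a shift of 0.17 over 14 members (camera adjusted p = 0.0309; 0.882 with an estimated correlation). In that list the integrin gene Itgb1 rose by 0.42 ± 0.09 (adjusted p = 0.0241), the only member to pass by either adjustment, and its other probes gave 0.47 and −0.46. Trp63 at 0.35 ± 0.10 (adjusted p = 0.0505), Bnc1 at 0.46 ± 0.15 (adjusted p = 0.0785) and Itga3 at 0.32 ± 0.13 (adjusted p = 0.143) did not pass on the probe used. Other probes of Trp63 gave 0.77 (adjusted p = 0.0437) and 0.47 (0.234), and those of Itga3 gave 0.55 (adjusted p = 0.0445) and −0.15 (0.652). The basement membrane list lost its call without enalapril 4 (0.0809), with array weights (0.0959), with the series matrix values (0.138) and with E1A control centring (0.0526), while its shift was 0.26, 0.28, 0.24 and 0.24. The basal keratinocyte list lost its call without vehicle 1 (shift 0.19, 0.119) or enalapril 3 (0.097, 0.0971), with the mean of a gene's probes (0.16, 0.251), the series matrix values (0.17, 0.172), E1A control centring (0.17, 0.0854) and the repaired normexp (0.047, 0.170). Itgb1 lost its call without vehicle 1, 2 or 4 or enalapril 1 or 3 (up to 0.0652). Normexp as planned, in which 6 spots distorted enalapril 3, turned the shifts of these lists to −0.029 and −0.20 and that of the collagens to −0.21. Adjusted p ran to 0.723 for basement membrane and 0.999 for basal keratinocytes over the alternatives.

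**Figure D3:**
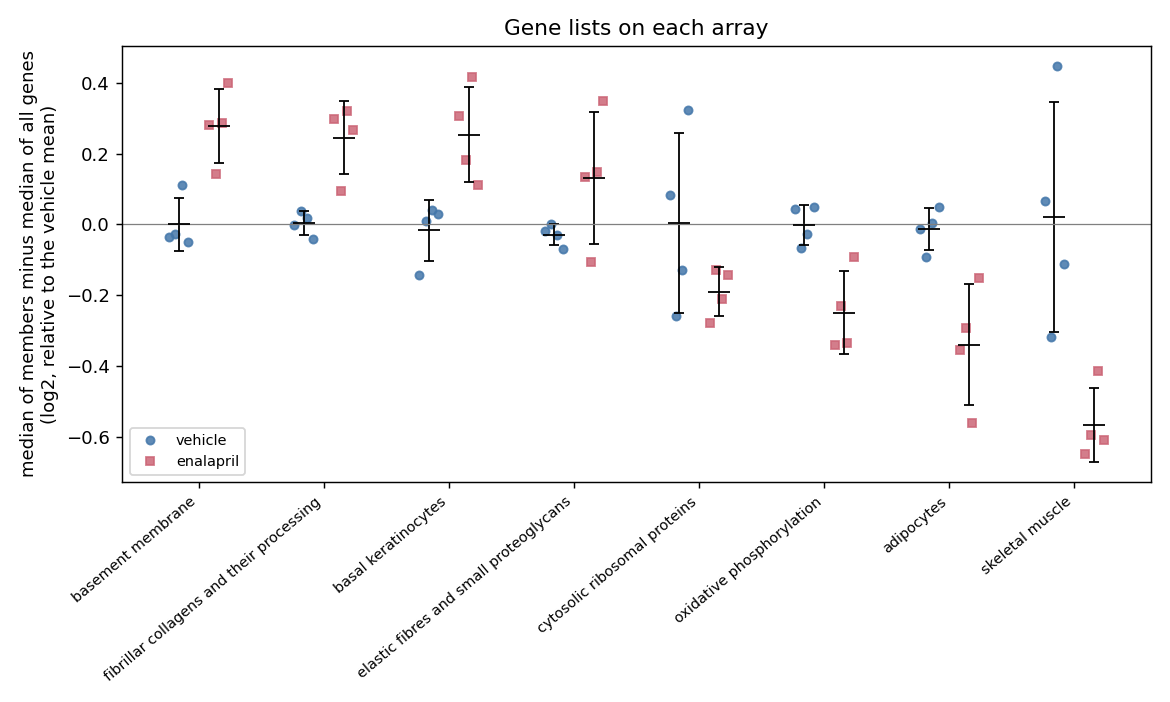
Median of the members of 8 gene lists on each array minus the median of all tested genes, in log2 relative to the vehicle mean, with points for arrays and the mean and SD as bars. The skeletal muscle list has the largest fall among the lists called, with a shift of −0.58. The basement membrane list is at 0.24 (0.26 by quantile normalization). The list of fibrillar collagens and their processing is at 0.21 (0.31 by quantile normalization).

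In the renin-angiotensin and kinin system, Agt fell by 1.00 ± 0.25 log2, or 1.99-fold, with all 4 enalapril arrays below all 4 vehicle arrays (adjusted p = 0.0336). With single arrays left out, Agt passed only without enalapril 4 (0.00857), and the other 7 fits gave adjusted p up to 0.0849. The adipocyte list stood lower on the same arrays (shift −0.38), and whether the fall of Agt goes with it was not tested. Ace, the gene of the inhibited enzyme, was at 0.13 ± 0.12 (adjusted p = 0.468), and the angiotensin receptor gene Agtr1a at −0.27 ± 0.15 (adjusted p = 0.242). The bradykinin receptor gene Bdkrb2 was at −0.86 ± 0.26 (adjusted p = 0.0576), and Nr3c2, the mineralocorticoid receptor, at −1.01 ± 0.34 (adjusted p = 0.0804). Lnpep was at 0.32 ± 0.12 (adjusted p = 0.0962). Of 19 members measured 1 fell and none rose over all genes, with 0 past the test adjusted over the list alone, and the list did not pass (shift −0.08, camera adjusted p = 0.689).

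Among genes of keratinocyte differentiation, 3 late cornified envelope genes passed the test. Lce1b fell by 0.76 ± 0.13 log2 (adjusted p = 0.0135), Lce1c by 0.57 ± 0.15 (adjusted p = 0.0374) and Lce1m by 1.15 ± 0.31 (adjusted p = 0.0444). Hrnr, which encodes hornerin, was at 0.47 ± 0.13 (adjusted p = 0.0505). Over all genes 3 of 29 members of the keratinocyte differentiation list fell, 1 did adjusted over the list alone, and the list did not pass (shift −0.03, or 0.03 by quantile normalization; camera adjusted p = 0.719) except with normexp as planned (−0.40, 0.000238). Lce1b kept its call with each array left out, and its other probe gave −0.22 (adjusted p = 0.422). Lce1c lost it without vehicle 1, 2 or 4 or enalapril 1, 2 or 3 (up to 0.0936), and Lce1m without vehicle 2 or 4 or any enalapril array (up to 0.106).

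Among other skin structures, the hair shaft gene S100a3 fell by 1.04 ± 0.25 log2 (adjusted p = 0.0303) and the hair keratin Krt32 by 0.77 ± 0.20 (adjusted p = 0.0378). Msx2, at −0.47 ± 0.14 (adjusted p = 0.0596), and Krtap8-1, at −0.66 ± 0.25 (adjusted p = 0.103), did not pass. Over all genes 2 of 25 hair genes fell, with 0 adjusted over the list alone. The hair list had a shift of −0.38 that did not pass (camera adjusted p = 0.253). Over 22 alternatives the shift ran from −0.64 to −0.23 and the adjusted p from 0.00441 to 0.596, with the list passing in 6. The 6 were the fits without vehicle 4 (0.00486) or enalapril 2 (0.00666), with the series matrix values (0.0214), with every probe tested (0.0297), and with normexp as planned (0.00441) or repaired (0.0247). In the smooth muscle and pericyte list, Kcnj8 fell by 0.64 ± 0.10 (adjusted p = 0.0124) and Lmod1 by 0.58 ± 0.11 (adjusted p = 0.0158), and both kept their calls with each array left out, although another probe of Kcnj8 gave −0.21 (adjusted p = 0.228). Abcc9 there was at −0.37 ± 0.11 (adjusted p = 0.0612). Of 15 members 3 fell over all genes and 4 adjusted over the list alone (shift −0.12, camera adjusted p = 0.489), and the list passed only with normexp as planned (0.00366). In the sebaceous gland list, Dgat2 fell by 0.54 ± 0.10 (adjusted p = 0.0176), Mlxipl fell by 0.69 ± 0.15 (adjusted p = 0.0233) and Far2 rose by 1.06 ± 0.29 (adjusted p = 0.0444), while Acly was at 0.41 ± 0.17 (adjusted p = 0.146). By both adjustments 1 of 18 sebaceous genes rose and 2 fell (shift 0.16, camera adjusted p = 0.393), and a second probe of Far2 gave −0.03, while the other probes of Dgat2 gave −0.14 (adjusted p = 0.349) and −0.05 (0.831). S100a3 lost its call without vehicle 1, 3 or 4 or enalapril 1 or 3 (up to 0.0790), Krt32 without any vehicle array or enalapril 1 or 3 (up to 0.0959), Dgat2 without vehicle 2 or enalapril 1 or 2 (up to 0.0536), and Mlxipl without vehicle 1 or enalapril 1, 2 or 3 (up to 0.0645). Far2 kept it only without enalapril 4 (otherwise up to 0.106).

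Immune and stress lists showed changes of single genes in both directions. Among macrophage genes, Chil3 rose by 0.96 ± 0.19 log2 (adjusted p = 0.0193) and the integrin Itgam by 0.58 ± 0.13 (adjusted p = 0.0248), while the complement gene C1qc fell by 0.52 ± 0.12 (adjusted p = 0.0255). Cd163 was at −0.43 ± 0.13 (adjusted p = 0.0561). Of 20 macrophage genes 2 rose and 1 fell over all genes, and 2 rose and 3 fell adjusted over the list alone (shift −0.04, or 0.03 by quantile normalization; camera adjusted p = 0.745). Among cytokines, Tslp fell by 0.71 ± 0.19 (adjusted p = 0.0403), Il1f8, which encodes IL-36 beta, fell by 0.57 ± 0.15 (adjusted p = 0.0377), and Il18 was at −0.38 ± 0.12 (adjusted p = 0.0776). With Il20 the cytokine list had 1 rise and 2 falls among 24 by both adjustments (shift 0.04, camera adjusted p = 0.786). Chil3 lost its call without vehicle 4 or enalapril 3 (up to 0.0523), Itgam without vehicle 1 or 2 or enalapril 1 or 2 (up to 0.0679), and C1qc without vehicle 1, 2 or 4 or enalapril 1, 2 or 3 (up to 0.0712). Tslp lost it without any vehicle array or enalapril 1 or 3 (up to 0.0990), and Il1f8 without vehicle 1, 3 or 4 or enalapril 1, 2 or 3 (up to 0.0924).

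In the oxidative stress list the glutathione synthesis gene Gclm rose by 0.74 ± 0.17 log2 (adjusted p = 0.0261), whereas Gstm1 fell by 0.69 ± 0.16 (adjusted p = 0.0263), Sod1 by 0.54 ± 0.12 (adjusted p = 0.0266) and Gpx1 by 0.45 ± 0.11 (adjusted p = 0.0345). Of 22 members 1 rose and 4 fell over all genes, and 1 rose and 5 fell adjusted over the list alone. Other probes gave −0.08 for Gstm1 (adjusted p = 0.811) and −0.16 and −0.07 for Sod1, neither past the test. The list did not pass (shift −0.03, or 0.10 by quantile normalization; camera adjusted p = 0.719). Proliferation genes also split. The mitotic activator Cdc20 fell by 0.77 ± 0.16 (adjusted p = 0.0213), while Top2a rose by 0.58 ± 0.12 (adjusted p = 0.0222), Rrm2 by 0.44 ± 0.10 (adjusted p = 0.0256) and the mitotic kinesin Kif11 by 0.53 ± 0.15 (adjusted p = 0.0484). By both adjustments 3 of 26 rose and 1 fell, and the list's shift of −0.02 had the opposite sign to the camera test and was 0.05 by quantile normalization (camera adjusted p = 0.719). Another probe of Top2a gave 0.32 (adjusted p = 0.667). With single arrays left out, Gclm, Gstm1, Sod1, Top2a and Rrm2 kept their calls only without vehicle 3 or enalapril 4, and Gpx1 only without vehicle 2 or enalapril 4 (otherwise up to 0.0922). Cdc20 lost its call without vehicle 2 or 4 or enalapril 2 or 3 (up to 0.0587), and Kif11 kept it only without enalapril 4 (otherwise up to 0.118).

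The largest rise of any named gene belonged to Tfap2e, an AP-2 family transcription factor gene, at 3.48 ± 0.37 log2 or 11.2-fold (adjusted p = 0.00477), although its other tested probe gave 0.03 (adjusted p = 0.940). Klf2 rose by 2.02 ± 0.26, or 4.06-fold (adjusted p = 0.00794), on one probe and fell by 0.76 (adjusted p = 0.0268) on another. Ssb, an RNA-binding protein gene, rose by 1.50 ± 0.31 (adjusted p = 0.0202; another probe 0.57, 0.110), and the cytokine gene Il20 by 1.83 ± 0.49 (adjusted p = 0.0407), with Il20 well above background on 1 vehicle array. The other 8 of the 12 largest rises were not well above background on any vehicle array. Cyp2c55 was at least 1.49-fold higher (adjusted p = 0.00630), Scn10a at least 1.41-fold (adjusted p = 0.0102), Prr18 at least 1.33-fold (adjusted p = 0.0425) and Hmgcll1 at least 1.23-fold (adjusted p = 0.00638). The olfactory receptor genes Olfr1306, Olfr665 and Olfr357 were at least 1.26-fold (adjusted p = 0.0128), 1.21-fold (adjusted p = 0.00630) and 1.19-fold (adjusted p = 0.0188) higher, and Magef1 at least 1.06-fold (adjusted p = 0.00477). With the repaired normexp, Il20 was at 0.68 (adjusted p = 0.0554), Scn10a was not tested, and the other 7 genes dim in vehicle lay between 0.41 and 0.60 (adjusted p from 0.0502 to 0.162), none of them passing. Because normexp adds an offset that shrinks the log2 changes of dim probes, these sizes do not test the bounds. Il20 lost its call without vehicle 1 or 2 or enalapril 1, 2 or 3 (up to 0.0982), Ssb without vehicle 1 or enalapril 1, 2 or 3 (up to 0.0559), and Prr18 without vehicle 1, 3 or 4 (up to 0.1004).

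After Dbp, the largest falls of genes measured in both groups were those of Olfr126, by 2.06 ± 0.22 log2 (adjusted p = 0.00477), and Pgf, the placental growth factor gene, by 1.95 ± 0.25 or 3.86-fold (adjusted p = 0.00794). Cd5l, a macrophage gene, fell by 1.58 ± 0.34 (adjusted p = 0.0234). The melatonin receptor gene Mtnr1b fell by 1.89 ± 0.26 (adjusted p = 0.00853), Onecut3 by 1.79 ± 0.42 (adjusted p = 0.0280) and Kndc1 by 1.79 ± 0.34 (adjusted p = 0.0174), each being well above background on only 1 of 4 enalapril arrays, so the sizes are poorly measured. Another probe of Kndc1 gave 0.13 (adjusted p = 0.617). Not well above background on any enalapril array were Agr2, at least 4.31-fold lower (adjusted p = 0.0128), Dbx1, at least 3.35-fold (adjusted p = 0.00477), and Magea9-ps, at least 2.06-fold (adjusted p = 0.00447). Foxl2 was at least 1.94-fold lower (adjusted p = 0.00794) and Cryba2 at least 1.92-fold (adjusted p = 0.0208). Under normexp as planned, 9 of these falls turned positive, those of Dbp, Olfr126 and Pgf being the exceptions, and Foxl2 was at 0.077 after the repair. With the repaired normexp Agr2 was at −0.53 log2 (adjusted p = 0.131), Dbx1 at −0.35 (0.121), Cryba2 at −0.15 (0.643) and Magea9-ps at −0.027 (0.939), smaller than the bounds given, and none passed. Mtnr1b at −0.35 (0.239), Onecut3 at −0.11 (0.681), Kndc1 at −0.26 (0.392) and Cd5l at −0.61 (0.0908) did not pass either, while Olfr126 at −0.74 (0.0195) and Pgf at −1.61 (0.00649) did. The offset added in normexp shrinks the log2 changes of dim probes, so the smaller sizes there do not test the bounds. Onecut3 kept its call only without enalapril 4 (otherwise up to 0.0734), and Cd5l lost it without vehicle 1 or 2 or enalapril 1, 2 or 3 (up to 0.0616).

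The remaining lists did not pass. Relative to all genes, B and plasma cell genes were shifted by −0.41 and neutrophil genes by 0.26 (camera adjusted p = 0.253 for both), with 1 B cell gene falling by both adjustments. The neutrophil list passed without enalapril 3 (0.0370), in a range of 0.0370 to 0.775. Cholesterol synthesis genes were shifted by 0.16 (camera adjusted p = 0.313), with 1 of 18 rising by both adjustments. That list passed by quantile normalization (0.0174) and with every probe tested (0.0088), in a range of 0.0088 to 0.616. Matrix proteases were shifted by 0.17 (0.364), melanocyte genes by −0.25 (0.377), and Langerhans and dendritic cell genes by 0.19 (0.521). Stress-associated keratinocyte genes were shifted by 0.19 (0.489), with 1 of 20 falling by both adjustments. Fibroblast genes were shifted by −0.05, or 0.02 by quantile normalization (0.521; 0.0161 with normexp as planned), with 2 of 18 falling by both adjustments. Chemokines were shifted by −0.06, or 0.01 by quantile normalization, with 1 of 27 falling by both adjustments, and MHC class II genes by −0.11 (0.689 for both). T and NK cell genes stood at −0.04 and immediate early genes at 0.04 (0.689 for both), each with the opposite sign after the repaired normexp. Epidermal barrier lipid genes stood at 0.01, or −0.07 after the repaired normexp (0.717), with 2 of 15 falling by both adjustments. Genes of the p53 response stood at −0.03, with the opposite sign by quantile normalization and 1 of 23 falling by both adjustments (0.719), and passed only with normexp as planned, at −0.30. Interferon-stimulated genes stood at −0.06, endothelial genes at −0.03 and mast cell genes at −0.03 (0.719 for each). Over the alternatives their highest shifts were 0.07, 0.05 and 0.06, of the opposite sign. Peripheral nerve genes stood at 0.10 (0.786), with 1 of 10 falling by both adjustments.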

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

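The tests in this part that were chosen only after the result was seen are those of brightness for the oxidative phosphorylation and ribosomal protein lists. In each group of 4 arrays, an array was singled out where its gap to the nearest other made up most of the group's range. Of 284 groups looked at, 14 had such an array, and chance marks about 1 in 20 groups, or 14.2 here, so their number is no more than chance gives. That says nothing on any single array.

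For Dbp, enalapril 1 was at 1.07 log2, below the other 3 at 2.78 to 2.98, so the fall of this clock output gene was deepest there. Arntl on vehicle 4 was at −1.63, below the other vehicle arrays. Cidec on enalapril 4 was at 4.78, the enalapril array nearest to the vehicle level of this fat cell gene. Top2a on enalapril 4 was at −0.53, Msx2 on enalapril 1 at −3.33, and Tslp on enalapril 2 at −1.39. Nr3c2 on enalapril 2 was at −6.79, and Olfr126 on vehicle 1 at −3.20. Among list medians per array, matrix proteases on enalapril 1 were at 0.38 and the TGF-beta response on the same array at 0.32, both above the other 3. Chemokines on enalapril 3 were at −0.47, below the others, and basement membrane genes on vehicle 3 at 0.11, above the others. Vehicle 1 was at −34.7 on the first principal component, beyond the other vehicle arrays. Enalapril 4 had a median correlation of 0.982 with its own group, against 0.990 to 0.991 for the other enalapril arrays, and lay nearer to the vehicle arrays (mean distance 80.0) than to its own group (85.7). Among control spots, which enter the fits only where arrays are centred on them, the probe E1A_r60_n9 was 0.48 log2 higher in enalapril (6.09 against 5.61). That is the largest rise of 10 such probes, whose differences ran down to −0.91 and had a mean of 0.07. The mean hides a split by brightness. Probes with a vehicle level of −1.95 or above were all higher in enalapril, by 0.21 to 0.48. Those at −4.70 or below were all lower, by 0.09 to 0.91. The brightest of 5 equal classes of tested genes had a median log2 change of −0.19, so the bright control probes did not share that direction. The labels do not give their amounts, so they cannot decide on a brightness-dependent shift.

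Other splits of the 8 arrays into 4 and 4 were set against the real one. Only 1 of 35 splits, the real one, gave as many changed genes (2707, highest other 2), and 1 of 35 as many genes at an unadjusted p under 0.05 (6126, highest other 4061). That is the smallest share 35 splits allow, so it argues against chance without excluding it. Every other split mixes the slides, so a slide effect would give the same result. For the number of lists called, 25 of 35 splits gave 7 or more, the highest other being 14, so chance is not excluded there. List by list, as extreme a camera p came from 2 of 35 splits for oxidative phosphorylation, 3 for adipocytes, 4 for basement membrane, 5 for fibrillar collagens, 7 for skeletal muscle, 8 for basal keratinocytes and 15 for ribosomal proteins. Chance is therefore not excluded for any of these lists. In that order, the real −log10 of the camera p was 5.08, 3.12, 2.69, 3.36, 4.91, 2.23 and 3.54, against 5.19, 4.10, 4.68, 8.34, 11.8, 3.39 and 15.4 in the highest other split.

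The lists of oxidative phosphorylation and ribosomal proteins both stood lower than other genes, and both are bright. The median of the ribosomal list lay at the 40.41 percentile of 10000 random lists matched on signal, so a brightness-dependent shift between the slides may account for that list. The median of the oxidative phosphorylation list lay at the 0.8 percentile, below −0.33, the lower limit of the central 95% of matched lists, but quantile normalization ended its call, so brightness stays open there. The array that stands apart does not carry this fall. On enalapril 4 the oxidative phosphorylation list was at −0.09, against −0.34 to −0.23 on the other enalapril arrays. Without enalapril 4 the list had a camera adjusted p of 0.000148. Because this array had the smallest fall, leaving it out was unlikely to end the call. Less skeletal muscle or fat in the enalapril samples also stays open, since those lists fell on the same arrays (shifts −0.58 and −0.38), and no test set it apart. A slide effect on particular probes and an effect of enalapril on mitochondrial genes cannot be told apart, because each slide held 1 group.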

How the results depend on the processing

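Chosen after seeing the data were the fits with E1A control centring, with probes well above background on all 8 arrays, and with the repaired normexp; the other alternatives were planned. The separation of the groups, 16.0 as reported, was 10.2 with normexp as planned, 11.2 with the repair and 12.4 to 22.4 with single arrays left out. Its exact permutation p was 0.0286, the smallest 35 splits allow and so no measure of stability, except with a vehicle array left out (0.0571). Of 78 named genes past the test, 7 kept their call under every alternative but normexp as planned; E1A control centring ended 50 and the replicate block 44. Of 7 lists, skeletal muscle and adipocytes kept their call in every refit. No list was called with an estimated correlation (0) or by limma's fry (0), where 6126 genes had an unadjusted p under 0.05. At the preset correlation, 25 of 35 splits of the arrays gave 7 or more lists, the highest other being 14. Camera with the preset therefore called as many lists in most splits that mix the groups. The preset may thus be too low for these lists, which was not tested further.

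The number of changed genes, 2707 as reported, was 0 by limma after normexp as planned, with 2564 genes at an unadjusted p under 0.05. On enalapril 3, 6 spots with a far higher local background raised the 5th percentile of the corrected log2 signal to 9.88, against 5.90 to 6.06 on the other arrays, and with the repair it was 5.90 and 1995 genes changed. The count was 1496 with no filter on dim probes, where more genes were tested, 5936 with array weights and 382 with E1A control centring (3730 at unadjusted p); the cause was not tested. It was 4535 at an adjusted p under 0.10, 1360 with a fold of at least 1.5, and 844 to 4942 with single arrays left out, the highest without enalapril 4. With the replicate number as a replicate block it was 592. Correlations of same-numbered arrays after removing group means were −0.16, 0.05, 0.15 and −0.02, and 1 of 4 pairs fitted best with its own number. That gives no sign that the numbers pair the mice, but 4 pairs cannot exclude it. Slide and scan as blocks could not be fitted.

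Normexp as planned reversed these changes: Agr2 0.23, Dbx1 0.39, Cryba2 0.57, Mtnr1b 0.41, Magea9-ps 0.73, Onecut3 0.65, Kndc1 0.47, Foxl2 0.84 and Cd5l 0.040 log2, and the lists of fibrillar collagens −0.21, basement membrane −0.029 and basal keratinocytes −0.20. With the repair Foxl2 alone among the named genes past the test stayed reversed, at 0.077. Low signal limits the dim genes: 80 changed genes were not well above background on any array of 1 group. Other tested probes of changed genes numbered 1038, of which 827 had the same direction, 189 passed the same way and 13 passed the opposite way.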

Other observations

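The tests of the clock and of muscle and fat in this part were all chosen after the result was seen. Among the other members of the clock list, chosen after their values were seen, some passed and others did not. Nr1d2, which encodes the repressor REV-ERB beta, fell by 0.99 ± 0.21 log2 (adjusted p = 0.0231), Hlf, a relative of Dbp, by 0.88 ± 0.20 (adjusted p = 0.0260), Bhlhe41 by 0.73 ± 0.16 (adjusted p = 0.0248) and Cry2 by 0.65 ± 0.18 (adjusted p = 0.0483). Ciart was at −1.05 ± 0.31 (adjusted p = 0.0577) and Nr1d1 at −0.58 ± 0.17 (adjusted p = 0.0590). Clock, the partner of BMAL1, was at 0.36 ± 0.11 (adjusted p = 0.0615), and Bhlhe40 at −0.33 ± 0.10 (adjusted p = 0.0650). Per3 at −0.97 ± 0.43 (adjusted p = 0.156), Npas2 at 0.41 ± 0.24 (adjusted p = 0.268), Per1 at −0.28 ± 0.25 (adjusted p = 0.464) and Cry1 at 0.20 ± 0.25 (adjusted p = 0.604) had overlapping groups.

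Single genes of lists that did not pass, also chosen after their values were seen, passed the test. The beta-defensin gene Defb14 fell by 0.75 ± 0.11 log2 (adjusted p = 0.0107), the eosinophil attractant Ccl24 by 0.85 ± 0.14 (adjusted p = 0.0128), the Schwann cell and melanocyte gene S100b by 0.59 ± 0.10 (adjusted p = 0.0140) and the B cell receptor gene Cd79b by 0.65 ± 0.14 (adjusted p = 0.0248). Lss, which encodes lanosterol synthase, rose by 0.52 ± 0.09 (adjusted p = 0.0138), and the proteoglycan gene Vcan by 0.54 ± 0.15 (adjusted p = 0.0463). Olfactory receptor genes changed in both directions: of 184 tested, 25 were higher and 15 lower, and 12 of these 40 were not well above background on any array of 1 group. That is 21.7% of these genes against 14.2% of all genes, at a median vehicle level of −5.13 log2. The difference was not tested. In the dimmest of 5 equal classes of tested genes, 266 of 3821 were changed and higher and 381 changed and lower.

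The median log2 change of the activators Arntl, Clock and Npas2 lay 1.29 above that of the other 13 clock genes, though Clock and Npas2 did not pass and Cry1, among the 13, was at 0.20. The gap lay at the 99.99 percentile of 10000 draws matched on signal, whose central 95% ran from −0.53 to 0.48. That argues against a brightness-dependent shift between the slides. The contrast was formed after the values were seen, and the activator median is that of Npas2, whose groups overlapped. A single array does not account for the gap, since the lowest gap with 1 array left out was 1.10. Chance is not excluded for the clock list, since 7 of 35 splits gave as extreme a camera p, and the gap was not tested on other splits. Per array the gap was −0.25 to 0.32 in vehicle and 0.83 to 1.82 in enalapril. A shift of clock phase with enalapril is a candidate explanation, as is a different time of day at skin collection, which the labels do not give. Neither was tested, and a slide effect on these probes cannot be told apart from an effect of enalapril.

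Markers of skeletal muscle and fat were both lower, although 7 and 3 of 35 splits gave lists as extreme, so chance is not excluded for either. The median of each list lay at the 0 percentile of 10000 matched lists, and both stayed called after quantile normalization. That argues against a brightness-dependent shift as the whole cause, without excluding it. The matched lists drew each gene independently, whereas markers of a tissue may move together. Quantile normalization made the shifts smaller, at −0.45 for muscle and −0.27 for fat, against −0.58 and −0.38 as reported. Less muscle or less subcutaneous fat in the enalapril samples may account for the falls, through the depth of the skin sample or a change in the tissue. If the members were confined to the tissue, such a loss would lower all of them alike. Of the muscle genes 3 of 19, and of the fat genes 3 of 17, had a 95% interval that left out the median of their list. The cut-offs for this count were set after the result was seen. Whether the members are confined to those tissues was not tested, so the count cannot decide. A slide effect and an effect of enalapril on these genes cannot be told apart.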
